A study of Homo sapiens with 33 samples.

How the data were processed

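The series holds 33 single-cell RNA libraries of human bone marrow, 8 from healthy donors, 14 from people with monoclonal gammopathy of undetermined significance (MGUS, a precursor of myeloma) and 11 labelled as myeloma. Per the labels' protocols, frozen samples were thawed, CD138+ cells were removed by sorting from the myeloma samples only, and libraries were made with the 10x Chromium system. The authors deposited whole-number UMI counts per gene and barcode, with no normalization. Per the submitters' processing notes, Cell Ranger 1.2, Seurat and the hg38 build were used, and the headers of 5 files name Cell Ranger 3.0.0. These files are healthy libraries 6, 7 and 8 and MGUS libraries 13 and 14. Whether every library was counted with the same version is not given in the sources used here. In 26 libraries the deposited counts cover all 737280 barcodes of the kit, and in 7 libraries (4 healthy, 3 MGUS) they cover called cells only. All 5 files with a version in the header are of the latter form, so form and version cannot be fully separated. Groups were taken from the labels.

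Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial counts were kept. A call at an order of magnitude below the largest barcodes had been planned, with this fixed floor as its alternative. The roles were exchanged after the thresholds of the planned call were seen, which ran from 524 to 3586 UMIs and were set by the largest cells of each library. The mitochondrial limit removed 4044 barcodes. Doublets were scored with Scrublet within each library, and the highest scores were removed up to the number expected from loading, 0.8% per 1000 cells. This removed 726 cells (1.42%), while the automatic threshold of the caller marked 265. After that, 50304 cells remained.

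Libraries were compared by their barcodes and counts before any averaging. A pair of myeloma libraries shared 2232 of 2237 kept barcodes, where 6.89 were expected by chance, and the UMI totals of the shared barcodes correlated with r = 0.999 across cells. Their chi-square per degree of freedom over genes was 3.86, against 27.0 or more for other myeloma pairs. They were taken as 1 library deposited under 2 sample names, their mean was used, and myeloma counted 10 donors. A pair of MGUS libraries shared 419 barcodes, where 5.59 were expected, and these barcodes were left out of both.

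Cells were clustered with Scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm (leidenalg 0.10.2, resolution 1), without integration across donors. T and NK clusters were pooled and clustered again, with each gene centred and scaled within its library. The T-like, NK-like and naive/stem T-like classes were thus set relative to the mean of each library. Clusters were named "like" a cell type from marker genes fixed before the data were examined, and clusters without enough markers stayed unnamed. Unnamed clusters held 3.77% ± 2.58 (SD, n = 8) of kept cells in healthy donors, 5.63% ± 4.34 (n = 14) in MGUS and 4.19% ± 1.90 (n = 10) in myeloma. T-like cells include naive/stem T-like cells.

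Shares of 9 classes were computed per donor over kept cells other than erythroid-like, plasma-like and platelet-like cells, since the labels state a sort against CD138+ cells for 1 group only. The naive/stem T-like share was taken over T-like cells. Group means were compared with two-sided permutation tests, exact where a group held fewer than 10 donors and with 100000 resamples otherwise, and adjusted by Benjamini-Hochberg over 30 tests.

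For T-like, NK-like, monocyte-like and B-like cells, UMI counts were summed per donor, and a donor entered a class with at least 20 cells of it. Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, all 3 groups in 1 fit) in R 4.3.3, at a false discovery rate of 0.05. XIST, TSIX and Y-linked genes were removed before the fit. Fixed gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), adjusted over 327 tests of lists, classes and comparisons. Of 31 lists, the platelet RNA and neutrophil RNA lists had too few measured members for a test. Every list call was computed again with a correlation estimated from the data, and none held (lowest adjusted p = 0.753). A permutation test of the mean list level per donor was added after the list calls were seen, and none of its 327 tests passed (lowest adjusted p = 0.589, or 0.286 without 6 libraries that stand apart). The list calls are therefore given with their sizes as descriptions of these donors.

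Named genes were chosen by a rule fixed before the data were examined. It took, per class and comparison, the 3 largest changes in each direction among called genes of mean log2 CPM of at least 5, and the 2 members of each described list with the smallest p. It excluded free-RNA genes (those of the erythroid, immunoglobulin and platelet lists) from the largest changes, along with genes that only some people carry and clone-named genes. It always included TCF7 in T-like and NK-like cells and CD69, CXCR4 and PDCD1 in T-like cells. Genes outside the rule are marked where they are named.

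The gene test after the low-count filter was tested on simulated data, with 200 genes changed in counts drawn from the real means and library sizes. Genes were drawn independently, so a state shared by many genes of a library, as in the 6 libraries that stand apart, was not simulated. For T-like cells in myeloma against MGUS, 89.4% of 4-fold changes, 68.7% of 2-fold changes and 17.9% of 1.5-fold changes were recovered among 9390 genes. For B-like cells in that comparison the values were 78.8%, 14.9% and 1.49% among 5301 genes.

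Alternatives were RLE normalization, no low-count filter, DESeq2 1.42.0, the replicate number as a block, the form of the deposited file as a covariate or as a restriction to libraries with all barcodes, a depth covariate, cells with at least 1000 UMIs, kept doublets, another denominator, a centred log-ratio scale with a pseudocount of 0.5, and Leiden resolution 2. Added after seeing the data were the planned order-of-magnitude cell call, leaving out 6 libraries that stand apart, using 1 file of the library deposited under 2 names, keeping the shared barcodes in the denominator, and leaving out each myeloma donor in turn for genes and lists in B-like cells and for the shares of B-like and monocyte-like cells. The names of classes were rebuilt here from markers, so they may differ from those of the study.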

Results

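Bone marrow immune cells were profiled by droplet single-cell RNA sequencing in 8 healthy donors, 14 people with MGUS and 10 people with myeloma, after a library deposited under 2 myeloma names was counted once because its 2 files differed by less than other pairs of libraries did. The series title names stem-like and marrow-resident T cells, innate cells and myeloid cells as its subject. Deposited matrices held between 2563003 and 18786264 UMIs each, and the median depth of kept cells ran from 2295 to 10658 UMIs per library. Its median over libraries was 3308.5 UMIs in healthy donors, 2855.5 in MGUS and 3481.5 in myeloma. Kept cells numbered 318 to 2932 per library. Each donor was taken as a replicate, and no label named a date or batch. The labels state that CD138+ cells were sorted out of the myeloma samples alone, yet plasma-like cells made up over 10% of kept cells in 3 of 10 myeloma, 1 of 14 MGUS and 0 of 8 healthy libraries. Plasma-like cells were left out of the comparison. Expression is given in CPM, the UMI count of a gene per donor and class scaled to a common library total.

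The cells formed T-like, NK-like, B-like, B precursor-like, monocyte-like, conventional and plasmacytoid dendritic cell-like (DC-like), neutrophil precursor-like, stem/progenitor-like, erythroid-like, plasma-like and platelet-like classes. In 6 libraries, 1 of 8 healthy and 5 of 14 MGUS, over 50% of the T, NK, B and monocyte cells lay in clusters led by activation and stress genes. The lowest such percentage among these MGUS libraries was 59.0%, and the highest among all other libraries was 6.71%. No myeloma library was among the 6 (Fisher's exact test, myeloma against MGUS, p = 0.0530). A B-like and a monocyte-like cluster held mainly cells of these libraries.

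NK-like cells made up 16.1% ± 7.88 (SD, n = 10) of counted cells in myeloma, 8.29% ± 5.60 (n = 14) in MGUS and 11.6% ± 4.67 (n = 8) in healthy marrow. Naive/stem T-like cells, defined by genes such as CCR7, LEF1 and TCF7, made up 25.9% ± 13.7 of T-like cells in myeloma, 41.6% ± 15.3 in MGUS and 31.5% ± 10.3 in healthy marrow. B-like cells made up 6.29% ± 8.48 in myeloma, 15.5% ± 11.7 in MGUS and 13.5% ± 3.68 in healthy marrow, and the myeloma mean was 4.08% when 1 library was left out. Plasmacytoid DC-like cells, which are specialised in type I interferon production, made up 1.70% ± 1.98 in myeloma, 0.456% ± 0.485 in MGUS and 1.03% ± 0.680 in healthy marrow. Conventional DC-like cells, which present antigen to T cells, made up 1.04% ± 1.23 in MGUS and 2.35% ± 1.33 in healthy marrow. No difference passed adjustment over the 30 share tests. The smallest permutation p was that of NK-like cells in myeloma against MGUS (p = 0.0107, adjusted p = 0.184), where 9 of 10 myeloma donors lay over the MGUS median. The naive/stem T-like share in myeloma against MGUS had a permutation p of 0.0176 (adjusted p = 0.184), and 1 of 10 myeloma donors lay over the MGUS median. With T-like and NK-like cells together as denominator this difference went from -15.8 to -17.9 percentage points and passed (adjusted p = 0.0432). As NK-like cells averaged 16.1% in myeloma and 8.29% in MGUS, this denominator also takes in their difference. With all kept cells as denominator, conventional DC-like cells at 0.814% in MGUS against 2.24% in healthy marrow (exact permutation p = 0.00432) and plasmacytoid DC-like cells at 0.305% against 0.973% (exact permutation p = 0.00200) passed too (adjusted p = 0.0432 for both).

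Within libraries that held all barcodes, the naive/stem T-like share was 34.9% ± 4.82 (SD, n = 4) in healthy marrow, 41.7% ± 17.4 (n = 11) in MGUS and 25.9% ± 13.7 (n = 10) in myeloma. The NK-like share was 10.4% ± 6.26, 9.56% ± 5.67 and 16.1% ± 7.88 in the same order. Within libraries of called cells, the NK-like share was 12.8% ± 2.81 (n = 4) in healthy marrow and 3.63% ± 1.34 (n = 3) in MGUS, and the monocyte-like share was 11.7% ± 11.5 and 1.75% ± 2.65. No myeloma library was of that form, so the form and the group cannot be separated for myeloma there.

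**Figure D1:**
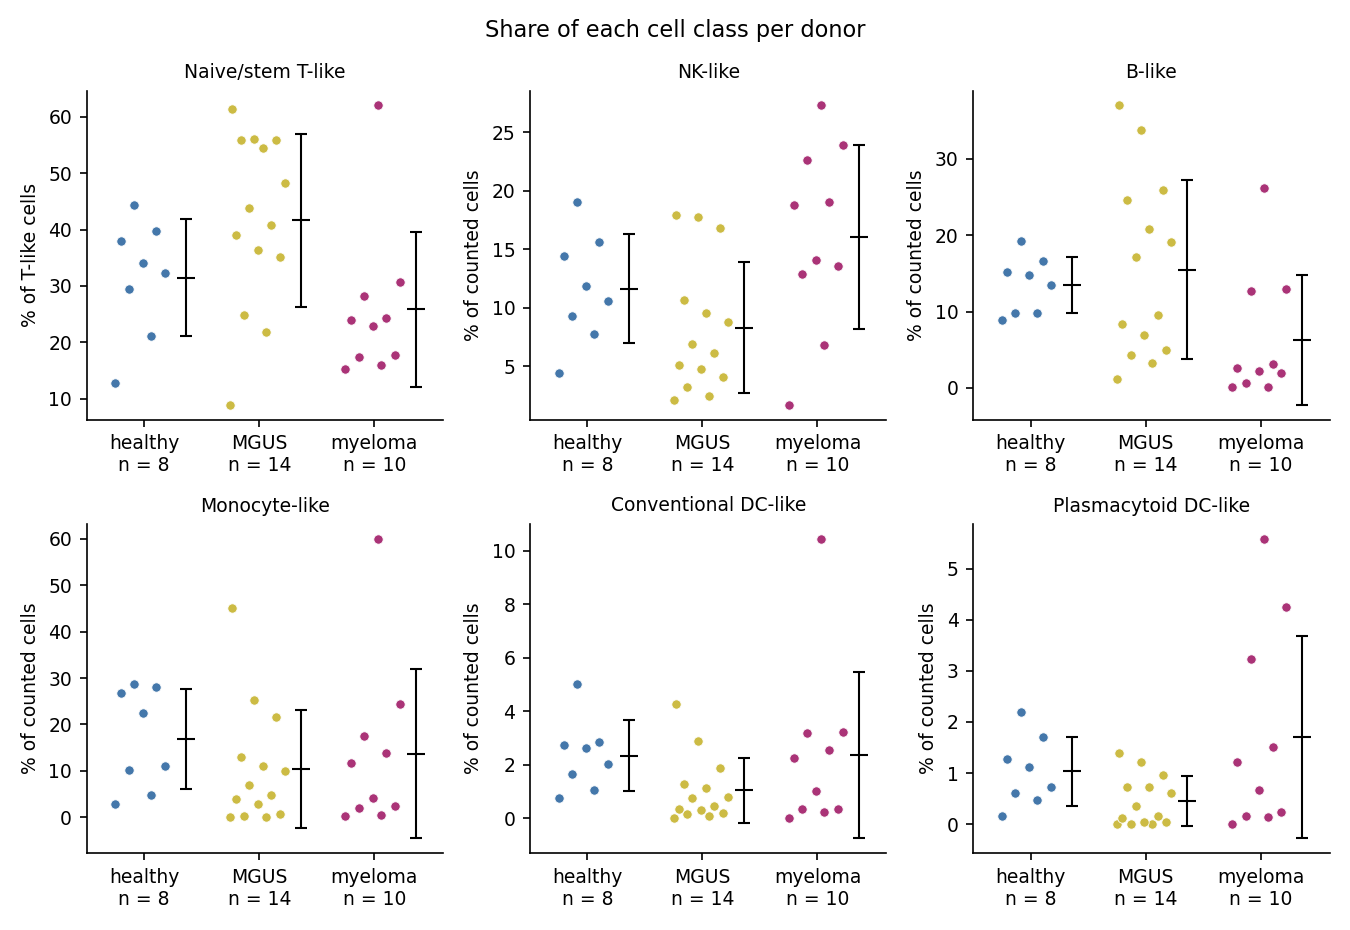
Share of 6 cell classes per donor, in percent of T-like cells for naive/stem T-like cells and in percent of counted cells for the others, with donors as points and bars for the mean and SD of each group. The myeloma mean of naive/stem T-like cells is 25.9%, against 41.6% in MGUS.

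The first comparison asked how the precursor state differs from healthy marrow in T cells. In T-like cells of MGUS, the list of naive/stem-like T genes was called higher and the cytotoxic effector list lower. Of the 17 naive/stem-like members, 15 had positive changes with a median log2 fold change of 0.22, and 1 rose when adjusted over the list alone (camera adjusted p = 0.00647). MAL, a membrane protein of resting T cells, had a log2 fold change of 0.90 ± 0.24 (SE; edgeR adjusted p = 0.419), and TCF7, a transcription factor of naive and stem-like T cells, had 0.48 ± 0.20 (adjusted p = 0.606). Mean TCF7 expression was 197.5 ± 57.5 CPM (SD, n = 14) in MGUS and 143.8 ± 40.8 (n = 8) in healthy donors, and 12 of 14 MGUS donors lay over the healthy median. Of the 21 cytotoxic members, 19 had negative changes with a median of -0.48 and none passed within the list (camera adjusted p = 0.000407). KLRD1, an NK receptor chain, had -0.73 ± 0.35 and PRF1, which encodes perforin, had -0.89 ± 0.44 (edgeR adjusted p = 0.630 and 0.636). The list of mature NK genes was lower too, with 13 of 14 members negative, a median of -0.49 and values of -1.05 ± 0.49 for PRSS23 and -0.90 ± 0.44 for ADGRG1 (camera adjusted p = 0.00423). Among libraries with all barcodes these 3 lists were not called (camera adjusted p = 0.391, 0.645 and 0.888), and the last 2 had the opposite direction.

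Immediate early and stress genes, which respond within minutes to stimulation or handling, were called higher in T-like cells of MGUS, with 21 of 22 members positive, a median of 0.68 and 1 that rose when adjusted over the list alone (camera adjusted p = 1.58e-05). ZFP36L1, an RNA-binding protein, had 0.72 ± 0.18 and its relative ZFP36 had 0.89 ± 0.40 (edgeR adjusted p = 0.337 and 0.627). The NF-kB and inflammatory list was higher with a median of 0.39, and TNF had 2.88 ± 1.04 and CD83 1.26 ± 0.56 (camera adjusted p = 0.0148). Without the 6 libraries that stand apart neither list was called (camera adjusted p = 0.150 and 0.788), and TNF had -0.49. CD69, an early activation and residency marker, had 1.01 ± 0.41, CXCR4, a marrow homing receptor, had 0.21 ± 0.34 and PDCD1, which encodes the PD-1 receptor, had -0.24 ± 0.38 (edgeR adjusted p = 0.605, 0.936 and 0.932). CXCR4 was at -0.49 and PDCD1 at 0.07 without the 6 libraries. Ribosomal protein genes, with 71 of 78 members positive, had a median of 0.24, and oxidative phosphorylation genes, with 30 of 34 positive, had a median of 0.17 (camera adjusted p = 5.43e-13 and 0.000719). RPS2 had 0.43 ± 0.15, while ATP5G2 had 0.29 ± 0.15 and NDUFB9 0.26 ± 0.13. Neither list was called among libraries with all barcodes (camera adjusted p = 0.0505 and 0.0902), where ribosomal genes had the opposite direction.

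Lists of RNA from other cells also differed in T-like cells of MGUS. Hemoglobin and other erythroid genes were higher, with 11 of 11 members positive and a median of 1.52, led by HBA2 with 2.27 ± 0.82 (camera adjusted p = 8.27e-07). Immunoglobulin genes were higher, with 10 of 10 positive, 3 that rose when adjusted over the list alone, a median of 1.98 and 4.44 ± 1.70 for IGLC3 (camera adjusted p = 0.000445). Monocyte genes were lower, with 7 of 7 negative and a median of -0.76, and the overlapping classical monocyte list had the same median (camera adjusted p = 0.000927 and 0.0126). S100A8, an alarmin, had -1.40 ± 0.83 and VCAN -1.51 ± 0.70. Without the 6 libraries the classical monocyte list was not called (camera adjusted p = 0.0594). Of the 11 lists, 8 were not called among libraries with all barcodes, as immediate early, inflammatory (in the opposite direction) and classical monocyte genes too had camera adjusted p of 0.573, 0.697 and 0.0952. All 11 list calls of this comparison were lost with an estimated correlation (adjusted p = 0.753 to 0.758). The edgeR quasi-likelihood test called 0 of 9390 genes, 731 had an unadjusted p under 0.05, and DESeq2 called 4.

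The comparison of myeloma with healthy marrow asked how T cells differ in the malignant state. In T-like cells of myeloma, MHC class II genes, which present antigen and mark activated T cells, were called higher, with 9 of 9 members positive, a median log2 fold change of 0.65 and 1 member that rose when adjusted over the list alone (camera adjusted p = 8.50e-05). HLA-DRB1 had 1.19 ± 0.37 and CD74, the invariant chain, had 0.81 ± 0.30. Inhibitory receptors were higher with 11 of 13 members positive and a median of 0.25, and TIGIT had 0.72 ± 0.29 and TOX, a factor of chronically stimulated T cells, 0.78 ± 0.35 (camera adjusted p = 0.0106). The latter call was lost without the 6 libraries that stand apart (camera adjusted p = 0.114). TCF7 was at 128.2 ± 39.1 CPM (SD, n = 10) in myeloma and 143.8 ± 40.8 (n = 8) in healthy donors, a log2 fold change of -0.16 ± 0.21. The naive/stem-like list was not called (median -0.16; camera adjusted p = 0.0859), and BACH2 had -0.98 ± 0.44 and S1PR1, the receptor for leaving tissues, -0.66 ± 0.26. CD69 had 0.84 ± 0.43, CXCR4 0.30 ± 0.36 and PDCD1 -0.03 ± 0.42.

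Immediate early genes were also called higher in T-like cells of myeloma than of healthy donors, with 17 of 22 members positive and a median of 0.30 (camera adjusted p = 0.000226), as DUSP1 with 1.36 ± 0.49 and ZFP36 with 0.96 ± 0.42. Early NK genes were higher with a median of 0.38, led by XCL1 with 1.49 ± 0.64 and COTL1 with 0.62 ± 0.26 (camera adjusted p = 0.0148). Mitochondrial transcripts had a median of 0.35 with MT-ND5 at 0.62 ± 0.21 and MT-CYB at 0.48 ± 0.22, oxidative phosphorylation genes had 0.19 with COX8A at 0.42 ± 0.19, and glycolysis genes had 0.09 with GAPDH at 0.54 ± 0.26 and GPI at 0.46 ± 0.19 (camera adjusted p = 2.27e-05, 3.34e-05 and 0.00868). The type I interferon list was called higher with 18 of 29 members positive and a median of 0.23 (camera adjusted p = 0.0480), although its members of smallest p, IFITM1 and OASL, had -1.34 ± 0.56 and -1.88 ± 0.82. Immunoglobulin genes were higher with a median of 2.38 and 6.00 ± 1.47 for JCHAIN (camera adjusted p = 0.0476). Of these lists, the immediate early, early NK, interferon, oxidative phosphorylation and mitochondrial ones were not called among libraries with all barcodes (camera adjusted p = 0.382, 0.0911, 0.0623, 0.0688 and 0.161). The interferon list was not called without the 6 libraries either (camera adjusted p = 0.149). With an estimated correlation all 9 calls were lost (adjusted p = 0.753). No gene of 9390 was called by edgeR, 370 had an unadjusted p under 0.05, and DESeq2 called 2.

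The comparison of myeloma with MGUS asked what separates the malignant from the precursor state. In T-like cells the naive/stem-like list was called lower in myeloma, with 13 of 17 members negative, a median log2 fold change of -0.64, and 8 members that fell and 1 that rose when adjusted over the list alone (camera adjusted p = 1.58e-05). TCF7 was at 128.2 ± 39.1 CPM (SD, n = 10) against 197.5 ± 57.5 (n = 14), a log2 fold change of -0.64 ± 0.19 (SE; edgeR adjusted p = 0.247), and 1 of 10 myeloma donors lay over the MGUS median. FOXP1, a factor of T cell quiescence, had -0.99 ± 0.26 (edgeR adjusted p = 0.185), and 0 of 10 myeloma donors lay over the MGUS median. Cytotoxic effector genes were called higher, with 18 of 21 members positive, a median of 0.58 and 5 that rose when adjusted over the list alone (camera adjusted p = 3.49e-06). GZMK, a granzyme, was at 373.2 ± 221.7 CPM against 185.3 ± 102.7, a log2 fold change of 1.02 ± 0.31, and CCL4, a chemokine, had 1.47 ± 0.46 (edgeR adjusted p = 0.279 and 0.287).

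Inhibitory receptors were called higher in the same comparison, with 12 of 13 members positive, a median of 0.64 and 4 that rose when adjusted over the list alone (camera adjusted p = 6.64e-05). TOX had 0.96 ± 0.31 and KLRG1, a receptor of differentiated T cells, 0.87 ± 0.31, while PDCD1 had 0.21 ± 0.38. MHC class II genes were called higher with 9 of 9 members positive, a median of 0.72 and 1 that rose when adjusted over the list alone, and HLA-DRB1 had 1.17 ± 0.31 and HLA-DMB 0.82 ± 0.31 (camera adjusted p = 3.09e-06). Tissue residency genes were called higher with 10 of 17 members positive and a median of 0.10 (camera adjusted p = 0.00411). CRTAM, an adhesion receptor, had 0.94 ± 0.29 and CXCR6, a chemokine receptor, 1.36 ± 0.50, while CD69 had -0.17 ± 0.37 and CXCR4 0.09 ± 0.31. Without the 6 libraries that stand apart CD69 was at 0.77 and PDCD1 at -0.06.

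Mitochondrial transcripts were higher in T-like cells of myeloma than of MGUS with 13 of 13 members positive and a median of 0.25, and MT-ND5 had 0.65 ± 0.18 (camera adjusted p = 5.09e-05). Ribosomal protein genes were lower with 72 of 78 negative and a median of -0.25, and RPL3 had -0.41 ± 0.14 (camera adjusted p = 3.60e-10). Hypoxia genes were lower with a median of -0.39, and MXI1 had -1.43 ± 0.35 and BNIP3L -0.61 ± 0.22 (camera adjusted p = 0.0276). Erythroid genes were lower with a median of -0.88, led by HBA1 with -1.36 ± 0.71 (camera adjusted p = 0.00911). The mitochondrial and hypoxia calls were lost without the 6 libraries (camera adjusted p = 0.136 and 0.814), the latter also among libraries with all barcodes (0.0982). With an estimated correlation all 9 calls were lost (adjusted p = 0.753). The edgeR test called 2 of 9390 genes, both higher in myeloma, and DESeq2 called 12. Both fall outside the rule for named genes because of their low level and were chosen after their values were seen. RASA1 (ENSG00000145715), a RAS GTPase-activating protein, was at 12.6 ± 5.19 CPM (SD, n = 10) against 5.16 ± 2.85 (n = 14), a log2 fold change of 1.33 ± 0.26 (SE; edgeR adjusted p = 0.0383). MTRNR2L1 (ENSG00000256618), a near copy of a mitochondrial ribosomal RNA whose reads may come from it, had 3.51 ± 0.66 (edgeR adjusted p = 0.0383), with 6 of 10 myeloma donors over the MGUS median. DESeq2 called RASA1 (DESeq2 adjusted p = 0.00333) but not MTRNR2L1 (DESeq2 adjusted p = 0.0953). Neither was called among libraries with all barcodes, where RASA1 was at 1.35 ± 0.28 and MTRNR2L1 at 4.46 ± 0.82.

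**Figure D2:**
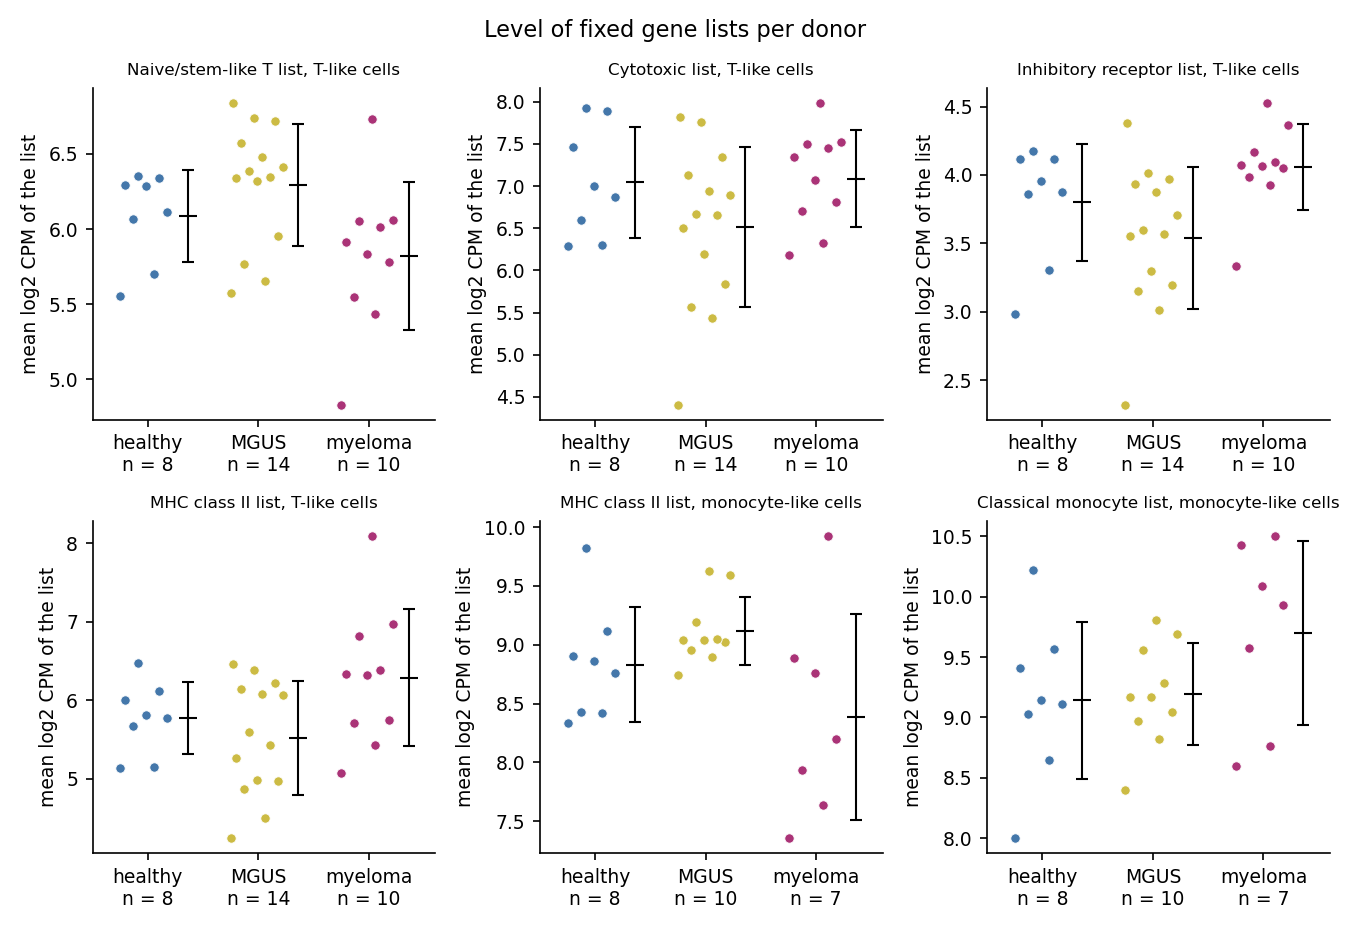
Mean log2 CPM of the members of fixed gene lists per donor, in T-like cells for the naive/stem-like, cytotoxic, inhibitory receptor and MHC class II lists and in monocyte-like cells for the MHC class II and classical monocyte lists, with donors as points and bars for the mean and SD of each group. In T-like cells 1 of 10 myeloma donors lies over the MGUS median of the naive/stem-like list.

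In NK-like cells of MGUS against healthy donors, early NK genes, which mark the less mature CD56bright cells, were called higher, with 12 of 14 members positive, a median log2 fold change of 0.31 and 2 that rose when adjusted over the list alone (camera adjusted p = 0.00474). TCF7, which early NK cells express, was at 103.9 ± 41.5 CPM (SD, n = 12) against 60.65 ± 30.96 (n = 8), a log2 fold change of 0.86 ± 0.27, and COTL1, an actin-binding protein, had 1.05 ± 0.26 (edgeR adjusted p = 0.369 and 0.329). Tissue residency genes had 12 of 12 members positive with a median of 0.56, as CD69 with 1.30 ± 0.44 and NR4A2 with 2.36 ± 0.78 (camera adjusted p = 0.00505). Immediate early genes had a median of 0.90 with FOS at 2.48 ± 0.78, and inflammatory genes had 1.02 with CCL3 at 2.26 ± 0.75 (camera adjusted p = 1.21e-05 and 0.0416). The last 3 calls were lost without the 6 libraries that stand apart (camera adjusted p = 0.700, 0.314 and 0.788). Higher were also genes of the suppressive myeloid list (median 0.54; LGALS3 0.85 ± 0.40), oxidative phosphorylation genes (median 0.14; COX7A2 0.28 ± 0.13), ribosomal protein genes (median 0.20; RPS2 0.42 ± 0.14) and erythroid genes (median 1.42; HBM 1.63 ± 0.67), with camera adjusted p of 0.0146, 0.0268, 1.10e-08 and 0.00868. The erythroid call was lost without the 6 libraries (camera adjusted p = 0.0603). Among libraries with all barcodes only early NK and erythroid genes stayed called higher (camera adjusted p = 0.0422 and 0.00905), and ribosomal genes were called lower (camera adjusted p = 0.0485). With an estimated correlation the 8 lists had adjusted p of 0.753 to 0.825. No gene of 4674 was called by edgeR, 439 had an unadjusted p under 0.05, and DESeq2 called 1.

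In NK-like cells of myeloma against healthy donors, early NK genes were again called higher, with 14 of 14 members positive, a median of 0.39 and 4 that rose when adjusted over the list alone (camera adjusted p = 0.00291). XCL1, a chemokine of early NK cells, had 2.26 ± 0.62 and GZMK 1.46 ± 0.52, while TCF7 had 0.07 ± 0.28. Tissue residency genes were higher with a median of 0.53, and CD69 had 1.55 ± 0.46 and EOMES, a factor of NK development, 0.85 ± 0.33 (camera adjusted p = 0.0106). Immediate early genes had a median of 0.89 with KLF6 at 1.32 ± 0.43, and mitochondrial transcripts had 0.44 with MT-ND5 at 0.77 ± 0.21 (camera adjusted p = 4.28e-05 and 3.37e-07). Ribosomal protein genes were higher with a median of 0.14 and RPL22L1 at 0.51 ± 0.25, while RPL17, whose reads can be split with a readthrough gene, had -0.52 ± 0.23 (camera adjusted p = 0.00162). Monocyte genes were lower with a median of -1.02 and LYZ at -1.49 ± 0.69 (camera adjusted p = 0.0416). Among libraries with all barcodes only the ribosomal list was called, in the opposite direction (camera adjusted p = 0.000302). The 6 lists had adjusted p of 0.753 to 0.828 with an estimated correlation. No gene was called by edgeR, 171 had an unadjusted p under 0.05, and DESeq2 called 1.

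In NK-like cells of myeloma against MGUS, edgeR called 2 of 4674 genes, both lower in myeloma, and DESeq2 called 7. SNHG7 (ENSG00000233016), a host transcript of small nucleolar RNAs, was at 47.1 ± 12.9 CPM (SD, n = 9) against 146.6 ± 106.8 (n = 12), a log2 fold change of -1.68 ± 0.33 (SE; edgeR adjusted p = 0.0434). FAM46A (ENSG00000112773), a poly(A) polymerase, was at 38.9 ± 17.5 CPM against 118.7 ± 77.6, a log2 fold change of -1.51 ± 0.30 (edgeR adjusted p = 0.0434). For both, 0 of 9 myeloma donors lay over the MGUS median. TCF7 had -0.79 ± 0.26 (edgeR adjusted p = 0.300). Mitochondrial transcripts were called higher with 11 of 12 members positive and a median of 0.32, as MT-ND5 with 0.73 ± 0.19, and ribosomal protein genes lower with 52 of 77 negative and a median of -0.05, as RPL3 with -0.32 ± 0.12 (camera adjusted p = 0.000156 and 0.0126). These list calls had adjusted p of 0.753 and 0.841 with an estimated correlation. Without the 6 libraries that stand apart neither gene was called, with SNHG7 at -1.49 ± 0.33 and FAM46A at -0.83 ± 0.23, and the mitochondrial list had a camera adjusted p of 0.0649. With the replicate block, which keeps only donors whose number occurs in both groups, SNHG7 was at -0.83 ± 0.28. The ribosomal list had 0.0668 among libraries with all barcodes.

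In monocyte-like cells of MGUS against healthy donors, SNX3 (ENSG00000112335), a sorting nexin of the endosome, rose from 265.4 ± 47.9 CPM (SD, n = 8) to 453.6 ± 86.7 (n = 10), a log2 fold change of 0.77 ± 0.14 (SE; edgeR adjusted p = 0.0211), and 10 of 10 MGUS donors lay over the healthy median. The other called gene was the clone-named AC074117.10 (ENSG00000234072), outside the rule and chosen after its values were seen, which fell by 2.37 ± 0.46 on the log2 scale (edgeR adjusted p = 0.0307). Its call was lost without the 6 libraries that stand apart (-2.30 ± 0.48; edgeR adjusted p = 0.0747) and with median UMIs per cell as covariate (edgeR adjusted p = 0.0508). DESeq2 called 28 genes. Inflammatory genes were called higher with 18 of 21 members positive and a median of 0.80, and CCL3, a chemokine, had 2.41 ± 0.76 and NFKBIA, an NF-kB inhibitor, 1.15 ± 0.44 (camera adjusted p = 0.00224). Immediate early genes were called higher with a median of 0.40 and 6 of 21 members that rose when adjusted over the list alone, as EGR1 with 2.43 ± 0.70 and ZFP36 with 0.94 ± 0.22 (camera adjusted p = 0.00179). MHC class II genes were not called (median 0.28; camera adjusted p = 0.0517), with HLA-DRA at 0.37 ± 0.19 and CD74 at 0.39 ± 0.22. Oxidative phosphorylation genes had a median of 0.13 with COX7A2 at 0.37 ± 0.12, ribosomal protein genes 0.10 with RPS2 at 0.42 ± 0.13, erythroid genes 2.47 with HBA2 at 3.33 ± 0.83, and immunoglobulin genes 3.01 with IGLC3 at 5.28 ± 1.66 (camera adjusted p = 0.00790, 0.000261, 1.54e-06 and 0.0469). The 6 called lists had adjusted p of 0.753 to 0.825 with an estimated correlation. The immunoglobulin call was lost without the 6 libraries that stand apart (camera adjusted p = 0.274). Among the libraries with all barcodes, 4 of them healthy, SNX3 was at 0.85 ± 0.19 and AC074117.10 at -1.44 ± 0.50, and neither was called. There the inflammatory and oxidative phosphorylation calls were lost (camera adjusted p = 0.0784 and 0.213) and ribosomal genes were called lower (2.68e-05).

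In monocyte-like cells of myeloma against healthy donors, IFI30 (ENSG00000216490), a lysosomal thiol reductase of antigen processing, fell from 451.9 ± 107.7 CPM (SD, n = 8) to 164.5 ± 68.0 (n = 7), a log2 fold change of -1.44 ± 0.26 (SE; edgeR adjusted p = 0.0248), and 0 of 7 myeloma donors lay over the healthy median. AC074117.10 fell by 2.59 ± 0.51 on the log2 scale (edgeR adjusted p = 0.0416). Classical monocyte genes were called higher with 14 of 15 members positive, a median of 0.48 and 4 that rose when adjusted over the list alone (camera adjusted p = 6.64e-05). S100A9, an alarmin, had 1.01 ± 0.33 and S100A12 1.21 ± 0.43. The overlapping list of monocyte RNA had a median of 0.45 (camera adjusted p = 0.00242). MHC class II genes were called lower with 7 of 9 members negative and a median of -0.24, and HLA-DRA had -0.24 ± 0.20 and HLA-DMB -0.44 ± 0.28 (camera adjusted p = 0.0444). Oxidative phosphorylation genes were higher with 31 of 34 positive and a median of 0.21, as SDHC with 0.52 ± 0.20, and erythroid genes had a median of 1.47 with AHSP at 2.35 ± 0.82 (camera adjusted p = 3.09e-06 and 0.000257). All 5 calls were lost with an estimated correlation (adjusted p = 0.753). Neither gene was called among libraries with all barcodes, where IFI30 was at -1.41 ± 0.32 and AC074117.10 at -1.76 ± 0.53. DESeq2 called 4 genes.

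In monocyte-like cells of myeloma against MGUS, MHC class II genes were called lower with 9 of 9 members negative, a median of -0.35 and 1 that fell when adjusted over the list alone (camera adjusted p = 1.54e-06). HLA-DRA was at 1644 ± 530.5 CPM (SD, n = 7) against 2499 ± 729.0 (n = 10), a log2 fold change of -0.60 ± 0.20, and HLA-DMA, which loads peptides, had -0.52 ± 0.22 (edgeR adjusted p = 0.613 and 0.637). Classical monocyte genes were called higher with 13 of 15 positive and a median of 0.62, as S100A9 with 0.78 ± 0.31 and the scavenger receptor CD163 with 1.90 ± 0.49 (camera adjusted p = 0.000118). Non-classical monocyte genes were called lower with 14 of 14 negative and a median of -0.55, as HES4 with -1.81 ± 0.75 and LYN with -0.59 ± 0.27 (camera adjusted p = 0.000108). Type I interferon genes were called lower with 22 of 23 negative and a median of -0.49, as IFIT2 with -1.78 ± 0.60 and EPSTI1 with -1.17 ± 0.47 (camera adjusted p = 0.0217). The inflammatory list was lower (median -0.38; NFKBIZ -0.74 ± 0.25), the mitochondrial list higher (median 0.26; MT-ND5 0.47 ± 0.19), the ribosomal list lower (median -0.08; RPS26 -1.02 ± 0.34) and the monocyte RNA list higher (median 0.58; S100A8 0.81 ± 0.35), with camera adjusted p of 0.0344, 0.00869, 0.0148 and 0.0263. The inflammatory and mitochondrial calls were lost without the 6 libraries that stand apart (camera adjusted p = 0.811 and 0.186). The interferon, ribosomal and monocyte RNA calls were lost among libraries with all barcodes (camera adjusted p = 0.0911, 0.0622 and 0.0982). With an estimated correlation the 8 lists had adjusted p of 0.753 to 0.839. No gene of 3894 was called by edgeR or DESeq2, and 280 had an unadjusted p under 0.05.

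In B-like cells of MGUS against healthy donors, immediate early genes were called higher with 19 of 20 members positive, a median of 0.86 and 4 that rose when adjusted over the list alone, as KLF6 with 1.12 ± 0.32 and DUSP1 with 1.11 ± 0.34 (camera adjusted p = 3.39e-09). Tissue residency genes had 8 of 8 members positive with a median of 0.57, and CD69 was at 566.4 ± 322.9 CPM (SD, n = 13) against 144.5 ± 103.0 (n = 8), a log2 fold change of 1.96 ± 0.42 (camera adjusted p = 0.000186). Unfolded protein response genes had a median of 0.20 with XBP1, a factor of secretory cells, at 0.90 ± 0.31 (camera adjusted p = 0.0204). The residency and unfolded protein calls were lost without the 6 libraries (camera adjusted p = 0.140 and 0.816). Ribosomal protein genes had a median of 0.17 with RPS2 at 0.37 ± 0.13, while RPL17, the member of smallest p, had -0.75 ± 0.20 (edgeR adjusted p = 0.539) and -1.02 without the 6 libraries (edgeR adjusted p = 0.0347). The medians were 1.44 for erythroid genes with HBA2 at 2.15 ± 0.80, -0.85 for classical monocyte genes and -0.92 for monocyte RNA, both with S100A8 at -1.98 ± 0.74. The camera adjusted p of these 4 lists were 1.07e-07, 1.97e-05, 0.00118 and 0.00108. The classical monocyte call was lost without the 6 libraries (camera adjusted p = 0.0854). Among libraries with all barcodes only erythroid and monocyte RNA stayed called. Immediate early, tissue residency, unfolded protein, classical monocyte and ribosomal genes, the last in the opposite direction, had camera adjusted p of 0.0759, 0.0583, 0.386, 0.0985 and 0.0525 there. The 7 lists had adjusted p of 0.753 or 0.754 with an estimated correlation. No gene of 5301 was called by edgeR, 300 had an unadjusted p under 0.05, and DESeq2 called 1.

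Few myeloma donors had enough B-like cells (n = 5). Against healthy donors, mitochondrial transcripts had a median of 0.54 with MT-CYB at 0.65 ± 0.25, oxidative phosphorylation genes 0.18 with COX7C at 0.41 ± 0.21, ribosomal protein genes 0.14 with RPS25 at 0.31 ± 0.18 but RPL17 at -0.40 ± 0.26, cytotoxic genes 0.51 with NKG7 at 0.96 ± 0.76, erythroid genes 1.05 with AHSP at 2.22 ± 0.90, immunoglobulin genes 0.88 with IGHA1 at 3.18 ± 0.79, and monocyte genes -1.55 with S100A8 at -1.84 ± 1.07. Their camera adjusted p were 2.11e-05, 0.000881, 4.50e-05, 0.0416, 0.0343, 0.0203 and 0.0252, and 0.753 to 0.825 with an estimated correlation. The cytotoxic call was lost without the 6 libraries (camera adjusted p = 0.206). The mitochondrial, ribosomal (in the opposite direction), immunoglobulin and monocyte calls were lost among libraries with all barcodes (camera adjusted p = 0.0545, 0.140, 0.0647 and 0.0525). Against MGUS, mitochondrial transcripts had a median of 0.39 with MT-ND5 at 0.67 ± 0.20, and cytotoxic genes, which B cells do not normally express, had 0.80 with GZMA at 1.62 ± 0.75 (camera adjusted p = 1.21e-05 and 0.00162). TGF-beta response genes had -0.78 with TGIF1 at -0.84 ± 0.40, immediate early genes -0.57 with BTG2 at -0.85 ± 0.33, and unfolded protein response genes -0.23 with DDIT3 at -1.77 ± 0.60 (camera adjusted p = 0.0148, 0.0221 and 0.0221), and these 3 calls were lost without the 6 libraries (camera adjusted p = 0.666, 0.678 and 0.986). The last 2 were also lost among libraries with all barcodes (camera adjusted p = 0.0836 and 0.0732). The 5 lists had adjusted p of 0.753 to 0.758 with an estimated correlation. In B-like cells edgeR called no gene in either comparison, 121 and 228 had an unadjusted p under 0.05, and DESeq2 called 0.

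**Figure D3:**
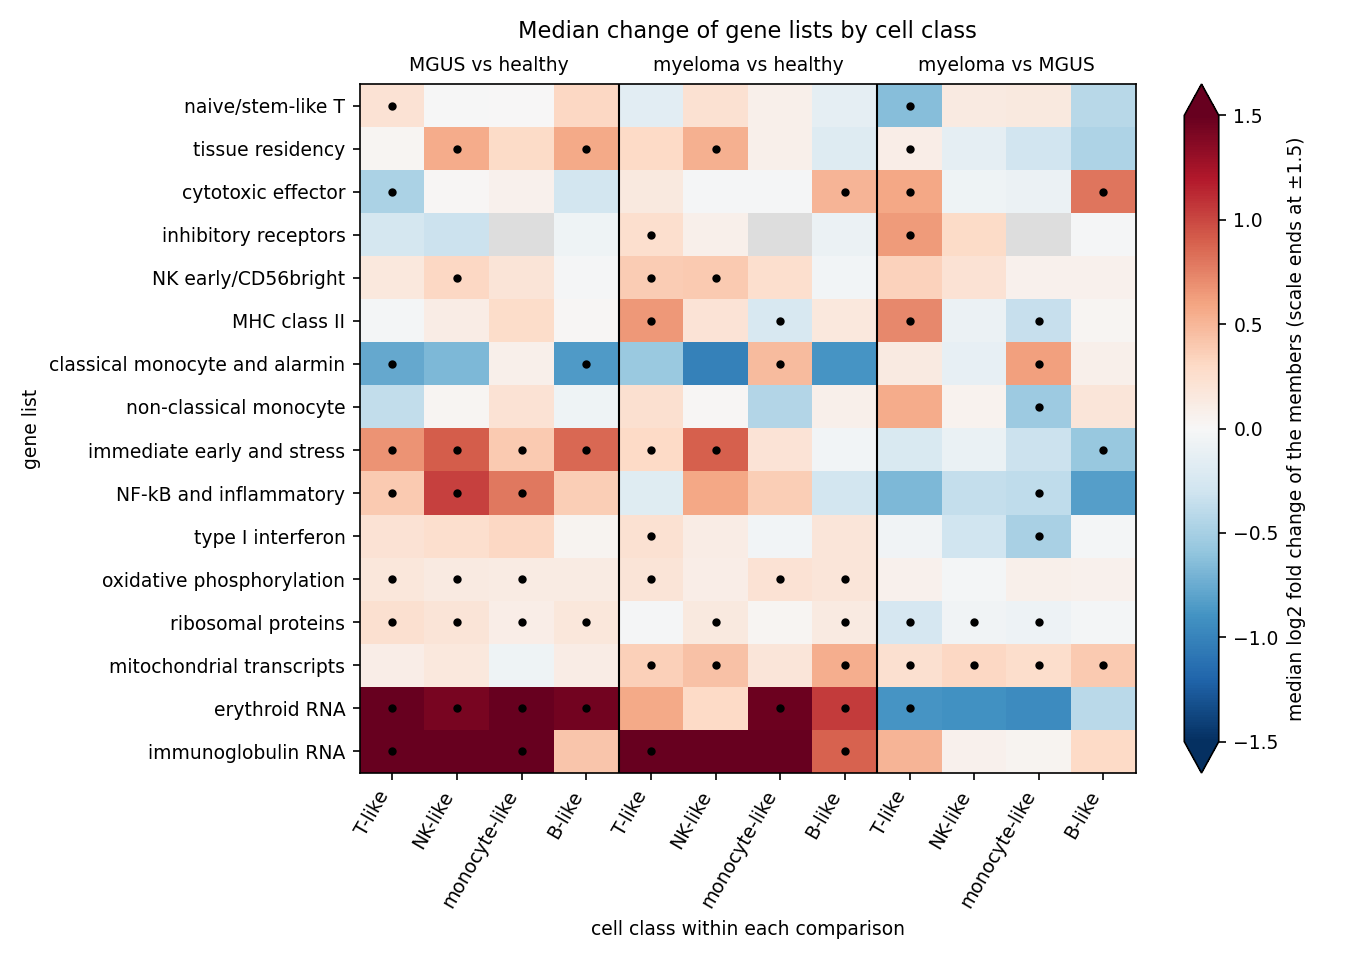
Median log2 fold change of the members of 16 gene lists in 4 cell classes and 3 comparisons, from lower (blue) to higher (red, saturated at the ends of the scale), with grey for too few measured members and dots for lists called with the preset correlation. None was called with an estimated correlation, and immediate early and stress genes have positive medians in all 4 classes of MGUS against healthy donors.

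Of the tested lists, 6 were called in no class and comparison. Their lowest camera adjusted p were 0.113 for proliferation genes, 0.147 for memory B cell genes, 0.251 for naive B cell genes, 0.182 for TNF superfamily and B cell survival genes, 0.0751 for T cell RNA and 0.0933 for B cell RNA in other classes.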

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

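The tests of the 6 libraries that stand apart, of the matrix form and of free RNA were chosen after the results were seen. So were those of the MHC class II difference between cell classes and of the cytotoxic list. Those of depth for the naive/stem-like list and of other splits of the donors were fixed before. The test of misplaced NK cells for the naive/stem-like list used a limit that rests on the size of the fall seen. That test is therefore not counted as fixed before.

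MHC class II genes went apart in T-like and monocyte-like cells. The mean log2 level of the list in T-like minus monocyte-like cells of the same donor was -1.92 ± 0.470 (SD, n = 7) in myeloma and -3.47 ± 0.623 (n = 10) in MGUS. The difference of 1.55 had an exact permutation p of 0.000103 (adjusted p = 0.0359 over 462 tests), and 7 of 7 myeloma donors lay over the MGUS median. Against healthy donors the difference was 1.14 (exact permutation p = 0.000155, the smallest that 7 against 8 donors can give; adjusted p = 0.0359). Free RNA entering all lymphocytes alike may be a candidate explanation of the T-like part, and it cannot be told apart from a change of T-like cells. The T-like minus NK-like level was higher in myeloma by 0.595 (exact permutation p = 0.0442; adjusted p = 0.620 over 462 tests), and by 0.441 without the 6 libraries that stand apart (exact permutation p = 0.179). The difference between T-like and monocyte-like cells was 1.42 without those libraries (exact permutation p = 0.000311), which argues against them as its cause. Only 2 of those libraries entered this comparison. The monocyte-like part alone was -0.685 without them (exact permutation p = 0.0538) and -0.730 with them, so most of its size stayed, but its p alone leaves their part open. As the difference was picked from 462 tests, its adjusted p of 0.0359 is what argues against a chance split of the donors. HLA genes differ in sequence between people, which was not tested, and a difference in T-like cell activation between the disease states stays open as untested biology. HLA-DRB1 and HLA-DQB1 were among the leading genes of T-like clusters other than the naive/stem ones. The naive/stem T-like share of T-like cells was 25.9% in myeloma and 41.6% in MGUS (adjusted permutation p = 0.184). The mix of T-like subsets was not tested for this list and cannot be told apart from a change within cells. With the preset correlation, classical monocyte genes were called higher and non-classical ones lower in monocyte-like cells of myeloma than of MGUS. The mix of monocyte subsets was not tested.

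Naive/stem-like T genes were called lower and cytotoxic genes higher with the preset correlation in T-like cells of myeloma than of MGUS. Neither call held with an estimated correlation, and neither list passed the adjusted permutation test of list levels. NK cells counted as T-like cells could dilute naive/stem-like genes, but the NK genes FCER1G, TYROBP, KLRF1, SPON2 and CLIC3 reached a median of 6.35% of their NK-like level in myeloma and 4.99% in MGUS, a difference of 1.36 percentage points, far below the 20 that such a dilution needs. The rise of the cytotoxic genes would need a median of 7.39 percentage points more NK-like RNA over 20 genes, while the rises of the 5 NK genes ran from -1.23 to 3.45. The needed median exceeded that of the NK genes by 6.80 (95% bootstrap interval over donors 1.03 to 13.6). This argues against NK cells that carry these 5 genes at the NK-like level, but not for the 4 of 20 genes that need 3.45 or less. The 5 genes were also among the markers that named NK-like clusters. NK cells low in them could stay in T-like clusters, so for either list such cells cannot be excluded by these values. With median UMIs per cell as covariate the naive/stem-like list stayed called lower (adjusted camera p = 6.53e-06) and the cytotoxic list higher (adjusted camera p = 3.17e-07). As neither call held with an estimated correlation, these values cannot decide on depth per cell. The 6 libraries are argued against for the naive/stem-like list by a level difference of -0.523 without them (permutation p = 0.0238), against -0.473 with them. For the cytotoxic list the difference was 0.366 without them (permutation p = 0.238) and 0.579 with them, so their part cannot be told apart. T-like cells include naive/stem T-like cells, which were named by genes of the same kind. Their share of T-like cells was 25.9% in myeloma and 41.6% in MGUS (adjusted permutation p = 0.184). The lower naive/stem-like list goes with this share, and a change of the cell mix cannot be told apart from one within cells. A composition of T cells that differs between the disease states stays open, as does the sort against CD138+ cells, which the labels state for myeloma alone.

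Immediate early and stress genes were called higher with the preset correlation in T-like, NK-like, monocyte-like and B-like cells of MGUS than of healthy donors. None of these calls held with an estimated correlation, and none passed the adjusted permutation test of list levels. The level differed by 0.431 in T-like, 0.649 in NK-like, 0.422 in monocyte-like and 0.610 in B-like cells. Among libraries with all barcodes it differed by 0.0266, 0.161, 0.362 and 0.214 in the same order (exact permutation p = 0.948, 0.708, 0.222 and 0.631). The drop in T-like, NK-like and B-like cells goes with a dependence on the form of the deposited libraries. In monocyte-like cells most of the difference stayed and the list stayed called (camera adjusted p = 0.0231). There 10 MGUS donors entered, against 14 in T-like cells, so the classes were compared on unlike sets of donors. With 4 healthy libraries the spread is too wide to decide in any of the 4 classes, so the form cannot be told apart from a difference between the groups. Without the 6 libraries the level differed by 0.121, 0.136, 0.414 and 0.429 (exact permutation p = 0.556, 0.544, 0.0723 and 0.0802), and the list stayed called in monocyte-like and B-like cells (camera adjusted p = 0.000299 and 0.000705). Of these 6 libraries, only 3 entered for monocyte-like cells, so leaving them out removed less there. All 6 were picked for clusters led by such genes, so their part cannot be told apart from biology. Neither handling nor thawing times are given in the labels.

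Splits of the donors, 70 per comparison with the real one among them, bear on chance only where the real split called genes. All numbers of splits given here, for genes and for lists, count the real one too. In myeloma against MGUS 7 splits in T-like cells and 4 in NK-like cells gave as many called genes as the real 2, with highest others of 22 and 32, so chance was not excluded for these genes. In monocyte-like cells 2 splits gave as many as the real 2 in MGUS against healthy, with a highest other of 47. In myeloma against healthy 1 split did, the real one with 2, with a highest other of 1. Both are under 5% of splits, which is weak against chance, as 16 such counts of genes and lists were compared. There 0 genes were called among libraries with all barcodes and with the replicate block. The fold of IFI30 was -1.41 and -1.48 in these 2 settings against -1.44, and that of SNX3 0.852 and 0.662 against 0.766, so the lost calls do not show that these changes depend on either. AC074117.10 shrank among libraries with all barcodes from -2.37 to -1.44 in MGUS and from -2.59 to -1.76 in myeloma. In the other 8 comparisons the real count was 0, which all 70 splits reach by definition, so they say nothing on chance. Their highest others were 606 in MGUS and 1 in myeloma against healthy for T-like cells, 142 and 21 for NK-like cells, 2 in myeloma against MGUS for monocyte-like cells, and 557, 0 and 415 for B-like cells. Splits that call many more genes than the real one point to a structure of the samples, and those with the highest counts placed 2 of the 6 libraries in the first group for T-like cells, 1 of 6 for NK-like and B-like cells in MGUS against healthy, and 4 of 5 for B-like cells in myeloma against MGUS.

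For called lists, in the same order of comparisons, 12, 27 and 33 splits gave as many in T-like cells as the real 11, 9 and 9, with a highest other of 16 each time. In NK-like cells 6, 30 and 70 splits gave as many as the real 8, 6 and 2, with highest others of 10, 10 and 13. In monocyte-like cells 16, 49 and 10 splits gave as many as the real 6, 5 and 8, with highest others of 11, 10 and 10. In B-like cells 18, 13 and 48 splits gave as many as the real 7, 7 and 5, with highest others of 13, 10 and 10. Chance was not excluded for any of these numbers of called lists.

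In libraries with all barcodes, barcodes of 1 to 50 UMIs, which hold mostly free RNA, had a median of 1.70% immunoglobulin RNA in MGUS and 1.58% in myeloma, against 0.168% in healthy marrow. Hemoglobin RNA made up a median of 4.90% in MGUS and 1.81% in myeloma, against 0.806% in healthy marrow. Of the 4 healthy libraries, the highest had 0.942% immunoglobulin RNA, which 10 of 11 MGUS and 8 of 10 myeloma libraries exceeded, and 8.94% hemoglobin RNA, which only 3 of 11 and 1 of 10 exceeded.

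One sample lay far from the rest of its group, by the gap to its neighbour over the range of the group, in 7 of 20 groups of shares and 20 of 246 groups of named genes. Chance gives about 1 in 20 for normally distributed values, which shares need not be. Groups of more than 10 donors were not tested, so MGUS was covered in monocyte-like cells alone. Among shares in myeloma the highest sample had a gap of 0.597 for monocyte-like, 0.508 for B-like, 0.822 for B precursor-like, 0.494 for stem/progenitor-like, 0.690 for conventional DC-like, 0.529 for neutrophil precursor-like and 0.669 for naive/stem T-like cells. In T-like cells the gaps in myeloma were 0.606 for MXI1, 0.615 for SLC25A37, 0.6254 for BACH2, 0.468 for GPI, 0.723 for IFITM1 and 0.534 for TIGIT, and in healthy donors 0.551 for CD69, 0.662 for CD83 and 0.595 for OASL. In NK-like cells they were 0.616 for FOS in myeloma, and 0.565 for KLF6 and 0.529 for RPL22L1 in healthy donors. In monocyte-like cells they were 0.553 for RPS2 and 0.492 for LYN in MGUS, 0.644 for SNX3 and 0.571 for SDHC in healthy donors, and 0.593 for MT-ND4L in myeloma. In B-like cells they were 0.552 for NR4A2 and 0.551 for CST3 in healthy donors and 0.749 for CDKN1A in myeloma.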

How the results depend on the processing

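The order-of-magnitude cell call, the analyses without the 6 libraries that stand apart, with 1 file of the library deposited under 2 names, with shared barcodes kept and without single myeloma donors, and the permutation test of list levels were added after the data were seen. Of the values recomputed, 338 shares and 2044 gene values kept their direction and their side of the threshold. In addition 93 gene counts and 63 counts of lists stayed within 1.5 times of the main count, which does not mean that the same genes or lists were called. In the main run no share passed, few named genes did, and most combinations of class and comparison had no called gene. Much of this is therefore values that stayed not called, which says little on robustness. In addition 23 gene values passed and 36 no longer passed the threshold. The cause of the changes below was not tested. B-like cells of myeloma had 5 donors, the fewest of the tested groups.

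With all kept cells as denominator, differences of shares in percentage points turned to -0.488 for B-like and -0.0632 for neutrophil precursor-like cells in MGUS against healthy, to -1.31 for B precursor-like and -0.379 for conventional DC-like cells in myeloma against healthy, and to -0.210 for B precursor-like cells in myeloma against MGUS. Naive/stem T-like cells over T-like and NK-like cells differed by -17.9 in myeloma against MGUS and passed, as did conventional DC-like cells at -1.43 and plasmacytoid DC-like cells at -0.668 over all kept cells in MGUS against healthy. The first of these differences also takes in that of NK-like cells. With the order-of-magnitude cell call, differences of MGUS against healthy turned to -0.350 for B-like, 0.908 for B precursor-like and 1.51 for stem/progenitor-like cells, and that of B precursor-like cells in myeloma against MGUS to -0.773. Stem/progenitor-like cells in MGUS against healthy turned to 0.0132 with cells of at least 1000 UMIs and to 0.469 without the 6 libraries. Conventional DC-like cells in myeloma against healthy turned to -0.0293 at Leiden resolution 2 and to -0.949 among libraries with all barcodes, where T-like cells turned to 3.60. On the centred log-ratio scale, MGUS against healthy turned to 0.126 for NK-like, 0.144 for B precursor-like, 0.586 for stem/progenitor-like and -0.0876 for neutrophil precursor-like cells. On that scale myeloma against healthy turned to 0.356 for T-like, -0.872 for B precursor-like and -0.184 for conventional DC-like cells, and myeloma against MGUS to -1.02 for B precursor-like cells.

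The replicate number was used as a block although no label says that the numbers pair the libraries. The 26 pairs with the same number had a mean r of 0.0529 and the 306 other pairs 0.00199. Of these, 12 of 26 and 86 of 306 had an r over 0.1. The difference was not tested, so pairing was neither shown nor excluded. Only donors whose number occurs in both groups entered, so MGUS donors numbered over 8 were left out against healthy donors. Changes with the block can therefore come from the donors left out. With this block, shares turned to -2.32 for B-like and 0.345 for stem/progenitor-like cells in MGUS against healthy, 1.46 for T-like and -1.98 for B precursor-like cells in myeloma against healthy, and -0.0840 for monocyte-like cells in myeloma against MGUS. With the replicate block edgeR called 0 genes in T-like cells of myeloma against MGUS (443 at an unadjusted p under 0.05), where RASA1 stayed at 1.37, and 1 in NK-like cells, which was neither of the 2 main genes. The replicate block gave 0 genes in monocyte-like cells of MGUS (351 unadjusted) and of myeloma (310 unadjusted) against healthy, and 2 in B-like cells of myeloma against healthy. Lists called with the replicate block numbered 5 in T-like and 3 in NK-like cells of myeloma against healthy, and 6 in NK-like and 3 in B-like cells of myeloma against MGUS. Log2 fold changes turned with the replicate block in T-like cells of MGUS against healthy to -0.61 for TNF, -0.0146 for CD83 and -0.56 for CXCR4, and to -0.11 for CXCR4 in myeloma against healthy and 0.23 for CD69 in myeloma against MGUS. With the block they also turned to -0.0847 for STAT3 in NK-like cells of MGUS, -0.20 for TCF7 in NK-like cells of myeloma and -0.0470 for JCHAIN in B-like cells of myeloma, each against healthy.

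Without a low-count filter edgeR called 2 genes in T-like cells of MGUS against healthy and 13 of myeloma against MGUS. For NK-like, monocyte-like and B-like cells, in MGUS against healthy, myeloma against healthy and myeloma against MGUS, it called 28, 9 and 46, then 38, 67 and 13, then 4, 3 and 4. DESeq2 called 4, 2 and 12 genes in T-like and 1, 1 and 7 in NK-like cells in the same order, 28 and 4 in monocyte-like cells of MGUS and of myeloma against healthy, and 1 in B-like cells of MGUS against healthy. RLE normalization gave 0 genes in NK-like cells of myeloma against MGUS by edgeR, with 520 at an unadjusted p under 0.05. With the matrix form as covariate 1 gene was called in T-like and 1 in NK-like cells of myeloma against MGUS, 4 in monocyte-like cells of MGUS against healthy and 0 of myeloma against healthy (352 unadjusted). Cells of at least 1000 UMIs gave 0 in T-like cells of myeloma against MGUS (974 unadjusted). With median UMIs per cell as covariate 0 genes were called in T-like (996 unadjusted) and 0 in NK-like cells (418 unadjusted) of myeloma against MGUS, 1 in monocyte-like cells of MGUS and 0 of myeloma (319 unadjusted) against healthy. With that covariate 2 lists were called in B-like cells of myeloma against MGUS, and CXCR4 in T-like cells of MGUS against healthy turned to -0.11. With 1 file of the library deposited under 2 names, 1 gene was called in monocyte-like cells of myeloma against healthy.

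Among libraries with all barcodes edgeR called 1 gene in T-like cells of MGUS and 1 of myeloma against healthy, and 0 of myeloma against MGUS (742 unadjusted). It called 0 in NK-like cells of myeloma against MGUS (423 unadjusted) and 0 in monocyte-like cells of MGUS (436 unadjusted) and of myeloma (399 unadjusted) against healthy. Lists called there numbered 5 in T-like, 5 in NK-like and 4 in B-like cells of MGUS against healthy, 1 in NK-like and 8 in monocyte-like cells of myeloma against healthy, and 1 in NK-like cells of myeloma against MGUS. In T-like cells of MGUS against healthy KLRD1 turned to 0.12, PRF1 to 0.20, PRSS23 to 0.20, ADGRG1 to 0.24 and CXCR4 to -0.0831, and CD69 in myeloma against MGUS to 0.00190. In NK-like cells STAT3 turned to -0.0690 in MGUS and TCF7 to -0.0878 in myeloma, both against healthy. With DESeq2 IGLC3 in T-like cells of myeloma against healthy turned to -0.0941.

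Without the 6 libraries that stand apart 2 genes were called in T-like cells of MGUS and 3 of myeloma against healthy. In NK-like cells 1 was called in MGUS and 1 in myeloma against healthy, and 0 in myeloma against MGUS (451 at an unadjusted p under 0.05 by edgeR). In B-like cells 7 were called in MGUS and 1 in myeloma against healthy. Lists called without them numbered 14 in T-like and 10 in monocyte-like cells of myeloma against healthy, 5 in NK-like cells of MGUS against healthy, and 7 in NK-like and 2 in B-like cells of myeloma against MGUS. TNF turned to -0.49, CXCR4 to -0.49 and PDCD1 to 0.0699 in T-like cells of MGUS against healthy, PDCD1 to 0.0103 in myeloma against healthy, and CD69 to 0.77 and PDCD1 to -0.0596 in myeloma against MGUS.

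With an estimated correlation, and with the permutation test of list levels per donor, 0 lists were called by camera and by the permutation test in each of the 12 combinations of class and comparison. Leaving out each myeloma donor in turn, the difference of the B-like share ran from -9.40 to -6.51 percentage points against healthy and from -11.4 to -8.53 against MGUS. The strongest against healthy passed (exact permutation p = 0.00165, adjusted p = 0.0494). The monocyte-like share ran from -8.29 to -1.67 against healthy and from -1.87 to 4.75 against MGUS, where the main difference was 3.27. In the same way edgeR called 0 genes in B-like cells of myeloma against healthy (122 to 304 unadjusted) and 0 against MGUS (179 to 266 unadjusted). Lists called ran from 3 to 6 against healthy, lowest without myeloma replicate 2 and with 4 without replicate 9, and from 3 to 7 against MGUS, lowest without replicate 1.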

Other observations

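No hypothesis is offered in this part, and its relations were chosen after the data were seen. RNA of other cells in a class rose with the free RNA of its library, by a positive Pearson's r, in all 12 relations within the disease groups, and 4 passed adjustment. None of these 4 was in monocyte-like cells, which had 9 libraries in MGUS and 7 in myeloma. A difference between classes was not tested. Over the 12 relations between the level of an erythroid or immunoglobulin list in a class and the share of that RNA in barcodes of 1 to 50 UMIs, adjusted p were under 0.05 in 4. For erythroid RNA in T-like cells Pearson's r was 0.740 in MGUS (permutation p = 0.0108, adjusted p = 0.0325; n = 11; Spearman's rho 0.691, p = 0.0223) and 0.879 in myeloma (permutation p = 0.00126, adjusted p = 0.00822; n = 10; rho 0.782, p = 0.0112), and 0.600 and 0.698 without the 2 farthest libraries. In NK-like cells of myeloma r was 0.886 (permutation p = 0.00137, adjusted p = 0.00822; n = 9; rho 0.850, p = 0.00568), and 0.732 without the 2 farthest libraries. For immunoglobulin RNA in T-like cells of myeloma r was 0.771 (permutation p = 0.0101, adjusted p = 0.0325; n = 10; rho 0.636, p = 0.0555), and 0.444 without the 2 farthest libraries. The other 8 had r from 0.459 to 0.934 and adjusted p from 0.0501 to 0.291, and r of 0.934, for immunoglobulin RNA in monocyte-like cells of myeloma, fell to 0.108 without the 2 farthest libraries.

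The difference in tissue residency genes between T-like and B-like cells of MGUS against healthy donors was -0.975 in the mean log2 level (exact permutation p = 0.000462; n = 13 and 8) and did not pass adjustment over 462 tests (adjusted p = 0.0711). The call of this list in B-like cells was lost without the 6 libraries that stand apart (camera adjusted p = 0.140) and among libraries with all barcodes (0.0583). In T-like cells of myeloma against healthy donors, tissue residency genes had a median log2 fold change of 0.30 with 11 of 17 members positive, and were not called (camera adjusted p = 0.0517). TGF-beta response genes in monocyte-like cells of myeloma against MGUS had a median of -0.63 with 7 of 8 members negative, and were not called either (camera adjusted p = 0.0778).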
